A study of Homo sapiens with 6 samples.

How the data were processed

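RNA was measured by sequencing in 6 libraries of HK-2 cells, an established human cell line derived from kidney proximal tubule epithelium. Per the labels, total RNA was taken with TRIzol and made into strand-specific Illumina libraries. The groups were read from the sample titles: 3 libraries came from control cells and 3 from cells given the growth factor GDF5, at 100 ng/ml for 48 hours per the series design text. Replicate numbers 1 to 3 were taken from the titles. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

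Per the submitters' processing notes, HISAT2, DESeq2 and the GRCh38 build were used, with no versions given there. The read counter, the annotation release and any filter are not given in the sources used here. The deposited table was present as 2 files with the same contents, and 1 was read. It lists 34157 genes, 25007 of them with a symbol.

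The 6 columns of values per library carry no unit in the header, and the values themselves showed that the authors deposited RPKM, that is reads divided by exon length and by the total of reads assigned to genes. For each gene with few reads the values were whole multiples of a step that depended on the gene and the library. A pair of further columns holds the authors' mean signal per group, which the values showed to be reads divided by a size factor per library and averaged over the group. The authors' log2 fold change of GDF5 over control and the authors' p-value and adjusted p-value per gene were deposited in the same table, per the file headers. These come from the authors' own comparison and are used here only where the authors' deposited table is named.

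The reads behind each RPKM value were recovered from the steps and the group means. All 64632 recovered values under 20 reads lay within 0.1 of a whole number, which is 100% of them. Of these 63.7% were even, so both mates of a pair may often have been counted. The share of such pairs was not measured. The implied gene length lay within 5% of the GENCODE 29 exon length for 80.6% of 11707 genes. Of the gene identifiers, 96.9% were found in GENCODE 29, and coordinates are given from that annotation on GRCh38. The recovered totals were used for depth, for the mitochondrial share and for an added limma-voom alternative, and never for the main test. Reads from overlapping genes and from near-identical copies may have been left out or split by the authors' counting, so low values of such genes are uncertain.

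The design fixed before the data were examined assumed counts, with a fallback for normalized values. Because the unit was RPKM and not counts, the fallback was used. Genes with a mean RPKM of at least 1 over the 6 libraries were tested, which left 12476 genes. Values were set to log2(RPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, no block and two-sided tests. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. Intervals are at 95%.

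Gene lists were tested with camera in limma on the same log2(RPKM + 1) values in place of the log2 CPM the design assumed. The preset correlation was 0.01, and p-values were adjusted over the 21 lists with at least 3 tested members out of 25 fixed lists. The same tests with an estimated correlation are given beside them. Members of a list are also counted after adjustment over the list alone. The genes named were chosen by a rule fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean RPKM of at least 2 and no overlap between the groups. It also took 20 genes fixed by name, up to 4 members of each list with the smallest adjusted p under 0.05, and the 2 members with the highest level from a list with no call. It named 115 genes, of which 107 were tested, and some of them are not reported here. Other members appear in counts or as examples, and they were chosen after their values were seen.

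The test was first tried on simulated data with 200 changed genes among the 12476. At folds of 1.25, 1.5, 2 and 4 it recovered 60%, 90%, 98% and 100% of the changed genes, with 8 false calls, 4.40% of the calls. With no change simulated it called 0 genes. In the simulation with 200 changed genes it called 0 of 100 unchanged lists. Genes were drawn independently, with changes balanced up and down and 1 common spread between libraries for all genes (dispersion 0.00099). The simulation therefore does not test lists whose members move together, or a shift in scaling. Nor does it test genes of wider spread or a library that stands apart, so recovery in the real data may be lower. The alternatives were another pseudocount, no filter, a filter on reads, a replicate block, a stricter threshold, another correlation and set test, and leaving out each library in turn. Median-of-ratios scaling of the RPKM columns, totals without mitochondrial reads and limma-voom on the recovered reads were added after seeing the data. Scripts were run in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.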

Results

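Gene expression was compared between control HK-2 cells and HK-2 cells given GDF5, a bone morphogenetic protein (BMP) family ligand. The series title places the question in diabetic kidney disease, where tubular cells may take on part of a mesenchymal state. The recovered reads assigned to genes came to 47972424, 45101766 and 56017280 in control replicates 1 to 3 and to 56038305, 43883468 and 54260684 in GDF5 replicates 1 to 3. No pair of libraries agreed within sampling noise: over 13007 genes the chi-square per gene, on reads divided by 2 to allow for counted mates, was 1.52 to 5.01 within groups and 17.2 to 24.1 between groups. The leading principal component held 53.6% of the variance and separated the groups. GDF5 replicate 1 stood apart in its group, with a chi-square per gene of 4.46 and 5.01 against GDF5 replicates 2 and 3, which were at 1.52 against each other.

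The largest rises among the called genes were in ID3, ID2 and ID1, inhibitors of DNA binding that are textbook targets of BMP signalling. ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515) went from 27.7 ± 1.47 to 186.2 ± 44.5 RPKM (SD, n = 3 each), a log2 change of 2.68 with a standard error of 0.15. ID2 (ENSG00000115738, chromosome 2, 8678845 to 8684453) went from 3.63 ± 0.237 to 30.2 ± 0.473 RPKM, a log2 change of 2.75 with a standard error of 0.04. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794) went from 9.37 ± 0.514 to 86.3 ± 15.4 RPKM, a log2 change of 3.06 with a standard error of 0.11. In GDF5 replicate 1 ID1 was at 237.5 RPKM, against 158.7 and 162.5 in GDF5 replicates 2 and 3. The vitamin D 24-hydroxylase CYP24A1 rose by 1.83 on the log2 scale, from 10.1 ± 0.123 to 38.4 ± 0.339 RPKM. The largest fall among the called genes was in MAL, a membrane protein of apical transport, from 16.2 ± 2.24 to 3.30 ± 0.358 RPKM, a log2 change of -2.00 with a standard error of 0.10.

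Of 12476 genes tested with limma, 3116 changed at an adjusted p under 0.05, 933 higher and 2183 lower, and 34 of them by at least 2-fold. At an unadjusted p under 0.05 there were 4906. The split depended on the scaling: with median-of-ratios scaling, added after seeing the data, 2848 genes changed, 1606 higher and 1242 lower, so that 56.4% of calls were higher against 29.9%. That scaling divided control libraries by 1.02 to 1.03 and GDF5 libraries by 0.980 to 0.985, which moved the median log2 change of all tested genes from -0.050 to 0.0021. The count fell to 2072 without control replicate 1, to 1760 without GDF5 replicate 2 and to 1866 without GDF5 replicate 3. The authors' deposited table gave 2982 genes an adjusted p under 0.05, of which 1677 were higher and 1305 lower. Of the 2752 of these tested here, 2076 were called here, all in the same direction. Another 1040 genes were called here and not by the authors, 1002 of them lower and 38 higher. With limma-voom and median-of-ratios scaling all 2752 were called. By the authors' log2 fold change 165 of their 2982 genes changed at least 2-fold. The 34 here leave out genes below the tested level and are on the log2(RPKM + 1) scale, which understates low genes.

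**Figure D1:**
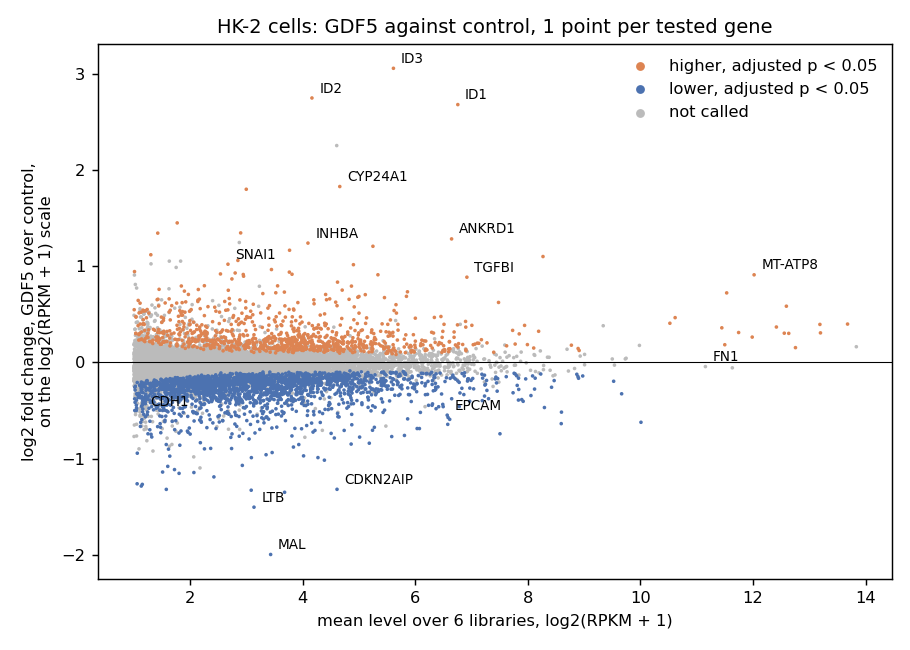
Each point is 1 of the 12476 tested genes, with its mean level as log2(RPKM + 1) on the horizontal axis and its log2 fold change of GDF5 over control on the vertical axis. Orange points are the 933 genes called higher, blue points the 2183 called lower and grey points the genes not called; ID1, ID2 and ID3 lie highest among the called genes.

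Among genes with a symbol, no overlap between the groups and a mean of at least 2 RPKM, the next rises were in MIR7856 (1.45), CRTAC1 (1.35), ANKRD1 (1.29), INHBA (1.24), TRNP1 (1.21) and UCA1 (1.17), all as log2 changes. ANKRD1, a cardiac ankyrin repeat protein, went from 57.2 ± 1.47 to 140.8 ± 2.83 RPKM, and INHBA, the activin A subunit, from 9.13 ± 0.239 to 23.0 ± 0.530 RPKM. By the same rule the next falls after MAL were in LTB (-1.51), SPNS2 (-1.35), SMPDL3A (-1.33), CDKN2AIP (-1.32), WNT7B (-1.19), SNORD117 (-1.15), SNORD6 (-1.15), HCG22 (-1.11) and MIR6859-3 (-1.08). LTB encodes lymphotoxin beta and went from 11.98 ± 1.24 to 3.56 ± 0.248 RPKM. The sphingosine-1-phosphate transporter gene SPNS2 went from 17.4 ± 1.40 to 6.19 ± 0.161 RPKM. MIR7856, SNORD117, SNORD6 and MIR6859-3 rested on a mean of 7, 9.5, 11.7 and 6.83 reads per library and were not called in the authors' deposited table, and MIR6859-3 has near-identical copies, so their values are uncertain. The call of MIR7856 ended with a pseudocount of 0.1 (limma adjusted p = 0.0847), without a filter (0.146) and without any library but control replicate 1 (0.0637 to 0.0958). The call of SNORD117 ended without a filter (limma adjusted p = 0.132) and without control replicate 1 (0.0847), control replicate 3 (0.0900), GDF5 replicate 2 (0.0540) or GDF5 replicate 3 (0.0831).

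Targets of BMP and SMAD1/5/9 signalling rose: all 7 tested members were called higher, and 7 when adjusted over the list alone. SMAD7 and SMAD6, inhibitory SMADs, rose by 1.06 and 0.74 on the log2 scale. The list was higher by camera (adjusted p = 7.52e-12, and adjusted p = 0.0131 with an estimated correlation). Another 8 members lay below the tested level, of which the authors' deposited table called 5 higher and 3, MSX1, DLX5 and TNFRSF11B, not. Among the 5, SMAD9 went from 0.209 ± 0.0205 to 1.41 ± 0.0887 RPKM and ATOH8 from 0.0974 ± 0.0134 to 0.629 ± 0.0604 RPKM, with adjusted p-values of 2.86e-53 and 5.13e-36 in the authors' deposited table. Of 11 tested genes for BMP ligands, receptors, SMADs and antagonists, 6 fell and 1 rose, with the same counts adjusted over the list alone. BMPR1B fell by 0.42, the antagonist GREM1 by 0.35, SMAD1 by 0.28 and SMAD4 by 0.25 on the log2 scale. The list as a whole was not called (adjusted p = 0.247 by camera). BMPR2 (0.096) and BMPR1A (0.028) were not called, and BMPR2 was called with limma-voom and median-of-ratios scaling (limma adjusted p = 0.00731). GDF5 itself was at 0.256 ± 0.0421 RPKM in control and 0.110 ± 0.0433 RPKM in treated cells, below the tested level.

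Targets of TGF-beta and SMAD2/3 rose, with 11 of 15 tested members higher, none lower, and 11 higher adjusted over the list alone. TGFBI went from 83.7 ± 0.739 to 155.7 ± 2.30 RPKM, a log2 change of 0.89. THBS1 (thrombospondin) rose by 0.69 and CCN2, connective tissue growth factor, by 0.54. The list was higher by camera (adjusted p = 5.30e-13, and adjusted p = 0.0131 with an estimated correlation).

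Among mesenchymal markers and transcription factors of epithelial-mesenchymal transition, 6 of 12 tested members rose and 1, S100A4 (-0.30), fell. Adjusted over the list alone, 7 rose and 1 fell. SNAI1, a repressor of CDH1, went from 3.20 ± 0.112 to 7.54 ± 0.563 RPKM, a log2 change of 1.02. SNAI2 rose by 0.46, CDH2 (N-cadherin) by 0.39 and the actin-binding gene TAGLN by 0.31. VIM had a log2 change of 0.088 (limma adjusted p = 0.0668), and was called with median-of-ratios scaling (limma adjusted p = 0.0141). FN1, at 2311 ± 69.8 and 2242 ± 22.9 RPKM, had a log2 change of -0.043, or 0.021 with median-of-ratios scaling, and was not called. ACTA2 was at 0.322 ± 0.0915 and 0.367 ± 0.0202 RPKM, below the tested level. The list was higher by camera (adjusted p = 0.000429), and adjusted p = 0.0814 with an estimated correlation ended the call.

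Epithelial junction and keratin genes were lower as a list by camera (adjusted p = 0.0368), and adjusted p = 0.257 with an estimated correlation ended the call. Of 19 tested members 10 fell and 2 rose, with the same counts adjusted over the list alone. EPCAM went from 111.5 ± 3.82 to 75.9 ± 1.32 RPKM, a log2 change of -0.55. CDH1 (E-cadherin) went from 1.62 ± 0.0354 to 0.834 ± 0.0255 RPKM, a log2 change of -0.51, and the tight junction gene CLDN1 fell by 0.39. The 2 that rose were KRT7 (0.42), a simple epithelial keratin, and TJP1 (0.36), the scaffold ZO-1. The list's call was lost without control replicate 3 (adjusted p = 0.0519 by camera), GDF5 replicate 2 (0.0515) or GDF5 replicate 3 (0.0599).

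**Figure D2:**
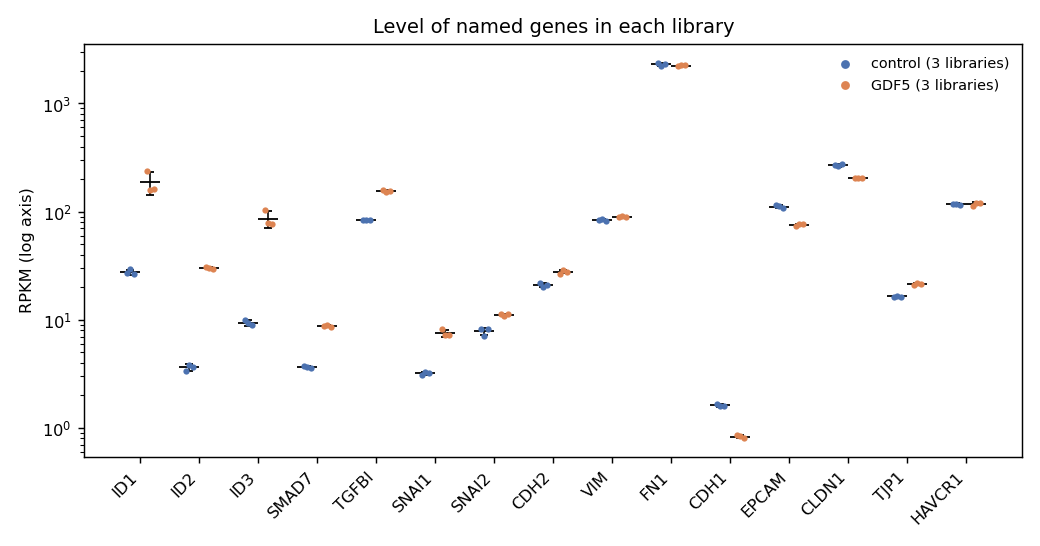
RPKM of named genes on a log axis, with 1 point per library, 3 control libraries in blue and 3 GDF5 libraries in orange; black lines are the mean and the SD. The groups stood apart for SNAI1 and CDH1 and lay close for FN1 and HAVCR1.

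Extracellular matrix genes went both ways, with 4 of 19 tested members higher and 6 lower, and the same counts adjusted over the list alone. Another 7 members lay below the tested level, of which the authors' deposited table called 1, COL5A1, higher and 6 not. COL5A1 went from 0.631 ± 0.0628 to 1.01 ± 0.0171 RPKM, with an adjusted p of 1.2e-08 in the authors' deposited table. FBN1 (fibrillin) rose by 0.43 and COL1A1 by 0.25 on the log2 scale, while LAMB3 fell by 0.59, TNC by 0.32 and LAMB1 by 0.24. The COL1A1 call ended without a filter (limma adjusted p = 0.0656), GDF5 replicate 2 (0.0593) or GDF5 replicate 3 (0.0667). With median-of-ratios scaling 5 members were higher and 5 lower. The list was not called (adjusted p = 0.959 by camera), its median of -0.020 and mean of -0.049 differed in sign from the test's direction, and the median was 0.042 with median-of-ratios scaling.

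Of 9 tested proximal tubule markers 3 fell, and 4 when adjusted over the list alone. Another 14 members lay below the tested level, of which the authors' deposited table called 1, ALPL, higher and 13 not. Among the 14 were LRP2 at 0.00092 RPKM and CUBN at 0.054 RPKM in control. GATM, of creatine synthesis, fell by 0.67, PAX8 by 0.42 and GGT1 by 0.25. The GGT1 call ended with median-of-ratios scaling (limma adjusted p = 0.0740), with mitochondrial reads left out of the totals (0.0553), without a filter (0.139) and without any library but GDF5 replicate 3 (0.0532 to 0.124). With that scaling 2 members were lower and 1 higher. The list was not called (adjusted p = 0.219 by camera). Of 13 tested injury and repair markers 5 fell and 1 rose, or 6 and 2 adjusted over the list alone. CLU (clusterin) fell by 0.85, SOX4 by 0.52 and DCDC2 by 0.52, and CD44 rose by 0.22. HAVCR1, a tubular injury marker, had a log2 change of 0.015, at 117.0 ± 2.52 and 118.3 ± 3.74 RPKM. LCN2 was at 1.23 ± 0.0917 and 0.417 ± 0.0346 RPKM, below the tested level; it was lower without a filter (limma adjusted p = 0.00696) and in the authors' deposited table (adjusted p = 1.9e-05). With median-of-ratios scaling 4 injury and repair markers were lower and 2 higher. The list was not called (adjusted p = 0.157 by camera).

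Among NF-kappaB and cytokine genes 10 of 19 tested members fell and 2 rose, or 11 and 3 adjusted over the list alone. CXCL3 fell by 0.59, CXCL8 (interleukin 8) by 0.59 and BIRC3 by 0.56, and CXCL8 went from 116.5 ± 1.75 to 76.9 ± 2.53 RPKM. The list was not called (adjusted p = 0.0693 by camera) but was called lower with median-of-ratios scaling (adjusted p = 0.0255 by camera), where 7 members were lower and 4 higher. With an estimated correlation and no such scaling its adjusted p = 0.348. Of 14 tested interferon-stimulated genes 4 fell and 1 rose, or 5 and 1 adjusted over the list alone, with IFIT2 at -0.33, IRF7 at -0.27, IFI35 at -0.21 and IFIT3 at -0.18. With median-of-ratios scaling IFI35 (limma adjusted p = 0.0597) and IFIT3 (limma adjusted p = 0.0578) were not called, which left 2 lower and 1 higher. Without GDF5 replicate 2 the calls of IRF7 (limma adjusted p = 0.0650) and IFI35 (0.0793) ended, without GDF5 replicate 3 those of IFI35 (0.0682) and IFIT3 (0.0567), without control replicate 1 those of IFI35 (0.0566) and IFIT3 (0.0512), and without a filter those of IRF7 (0.0688) and IFI35 (0.0769). The list was not called (adjusted p = 0.208 by camera).

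Mitotic genes rose by small amounts, with 18 of 22 tested members higher and none lower, or 19 higher adjusted over the list alone. AURKA rose by 0.32, MKI67 by 0.29, BUB1 by 0.27 and CCNA2 by 0.26 on the log2 scale. The list was higher by camera (adjusted p = 1.03e-13, and adjusted p = 0.0131 with an estimated correlation). Of 22 tested DNA replication genes 10 fell and none rose, or 11 fell adjusted over the list alone, among them MCM2 by 0.24 and PCNA by 0.15. With median-of-ratios scaling 5 were lower and 2 higher, and the list was not called (adjusted p = 0.175 by camera). Among p53 targets 7 of 18 fell, including CDKN1A (p21) by 0.50 and DDB2 by 0.31, and 1, PLK2, rose by 0.26. Adjusted over the list alone, 9 fell and 1 rose. The p53 list was lower (adjusted p = 0.0328 by camera), with adjusted p = 0.189 with an estimated correlation and adjusted p = 0.0519 without control replicate 3.

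**Figure D3:**
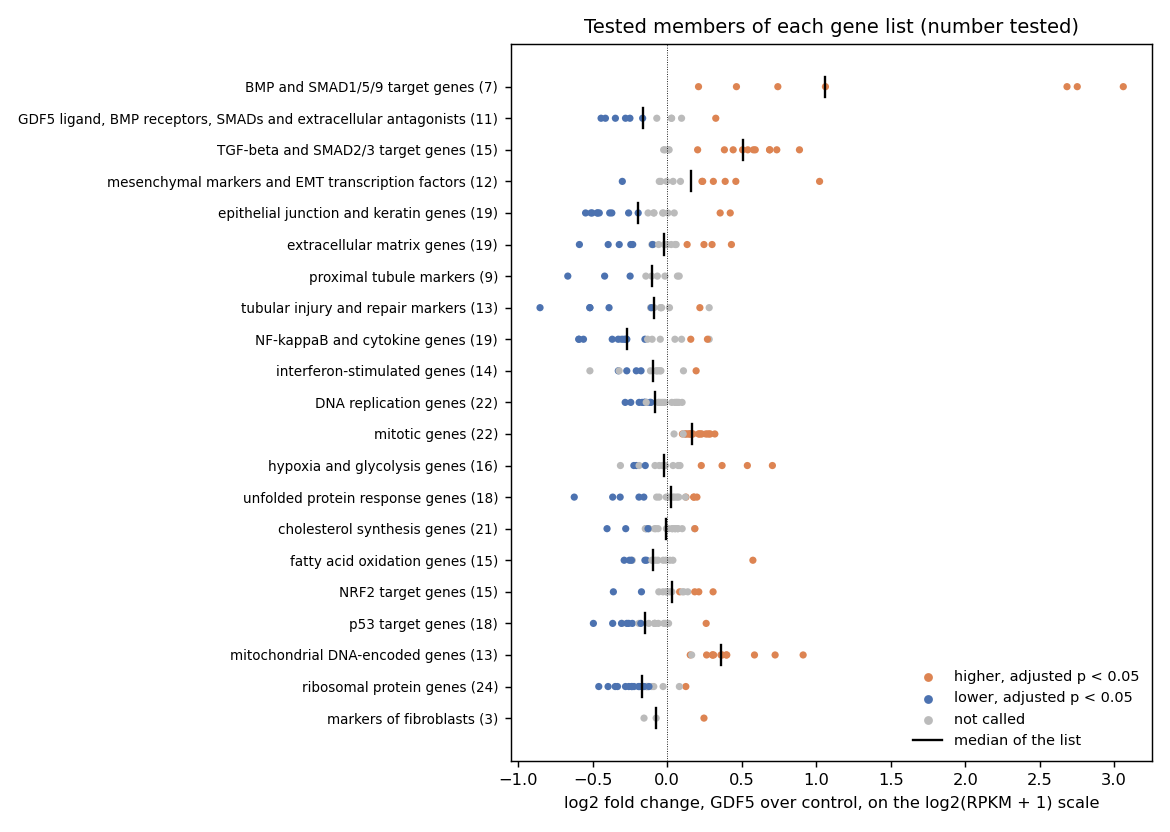
Log2 fold change of GDF5 over control for each tested member of the 21 tested lists, 1 point per gene, with orange points called higher, blue points called lower, grey points not called, and a black line at the list's median. The medians were 1.06 for BMP targets, 0.51 for TGF-beta targets and -0.20 for epithelial junction and keratin genes.

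Reads from mitochondrial DNA-encoded genes made up 8.27 ± 0.400% of reads in control and 10.2 ± 0.149% in GDF5 libraries (SD, n = 3 each). Of 13 mitochondrial protein-coding genes 12 rose and none fell, or 13 rose adjusted over the list alone. MT-ATP8 rose by 0.91, MT-ND6 by 0.72, MT-ND3 by 0.59 and MT-ND5 by 0.36. Without a filter the calls of MT-ND3 (limma adjusted p = 0.197) and MT-ND5 (0.142) ended. The list was higher by camera (adjusted p = 2.13e-12), and adjusted p = 0.178 with an estimated correlation ended the call. Of 24 tested ribosomal protein genes 16 fell and 1 rose, or 18 and 1 adjusted over the list alone, with RPS19 at -0.46. The ribosomal list was lower by camera (adjusted p = 5.46e-05), and adjusted p = 0.257 with an estimated correlation ended the call. With median-of-ratios scaling 11 were lower and 1 higher.

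**Figure D4:**
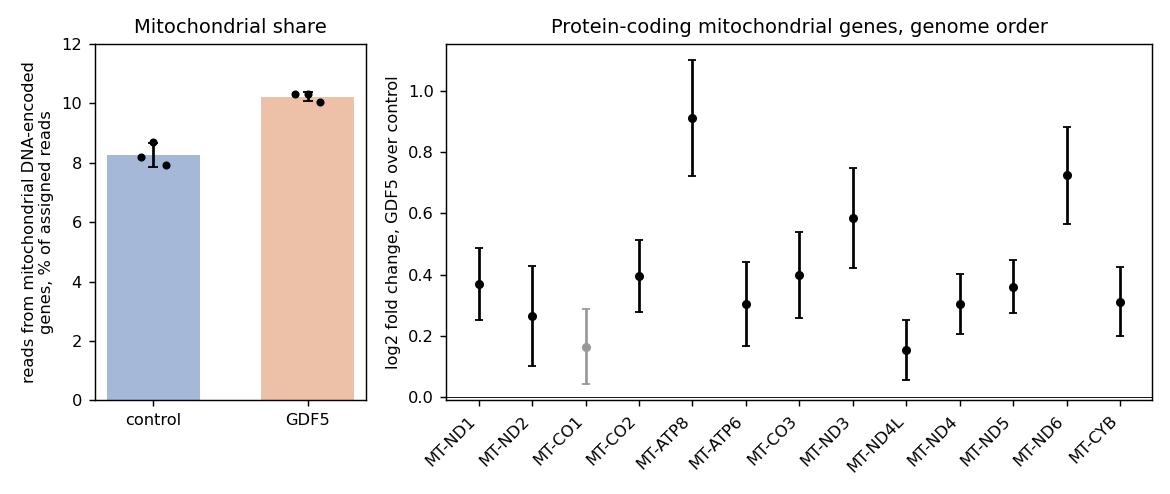
Left, percent of assigned reads from mitochondrial DNA-encoded genes, with bars at the mean, SD as error bars and 1 point per library. Right, log2 fold change of the 13 protein-coding genes with 95% intervals, black where called; the values ran from 0.15 for MT-ND4L to 0.91 for MT-ATP8.

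In the NRF2 list 4 of 15 tested members rose and 2 fell, with the same counts adjusted over the list alone. NQO1 rose by 0.21 and FTL by 0.18, and AKR1C3 fell by 0.36. The NQO1 call ended without GDF5 replicate 2 (limma adjusted p = 0.0562), GDF5 replicate 3 (0.0554) or a filter (0.0528), and those of FTL (0.464) and AKR1C3 (0.0615) ended without a filter. With median-of-ratios scaling 6 members were higher and 1 lower. The NRF2 list was higher by camera (adjusted p = 0.0284), with adjusted p = 0.257 with an estimated correlation, adjusted p = 0.0704 without control replicate 1 and adjusted p = 0.180 without a filter. Hypoxia and glycolysis genes went both ways, 4 higher and 3 lower of 16, or 4 and 4 adjusted over the list alone. PFKFB3 rose by 0.71, ANGPTL4 by 0.54 and LDHA by 0.37, and ENO2 fell by 0.21. That list was not called (adjusted p = 0.227 by camera), and its median of -0.022 differed in sign from its mean of 0.048 and was 0.041 with median-of-ratios scaling.

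Of 18 tested unfolded protein response genes 4 rose and 5 fell, with the same counts adjusted over the list alone. The chaperone genes CALR (0.18) and HSP90B1 (0.18) and the transcription factor gene ATF4 (0.20) rose, and TRIB3 (-0.62) fell. With median-of-ratios scaling 7 members were higher and 4 lower. The list was not called (adjusted p = 0.175 by camera, direction higher), and its median of 0.025 and mean of -0.041 differed in sign. Of 21 cholesterol synthesis genes 1 rose (STARD4, 0.19) and 4 fell, among them LSS by 0.28 and SREBF2 by 0.13, with the same counts adjusted over the list alone. With median-of-ratios scaling the balance turned, to 4 higher and 2 lower, and SREBF2 was not called (limma adjusted p = 0.158). The SREBF2 call also ended with mitochondrial reads left out of the totals (limma adjusted p = 0.0563), without a filter (0.0558) and without control replicate 1 (0.0676), control replicate 3 (0.0618), GDF5 replicate 2 (0.0937) or GDF5 replicate 3 (0.0866). The cholesterol list was not called (adjusted p = 0.798 by camera, direction higher), and its median of -0.0058 and mean of -0.038 had the other sign, the median being 0.054 with that scaling. Of 15 fatty acid oxidation genes 5 fell and 1 rose, with the same counts adjusted over the list alone. ECHS1 fell by 0.29, PDK4 by 0.25 and ECI1 by 0.24, and PPARGC1A, a coactivator of mitochondrial biogenesis, rose by 0.57. With median-of-ratios scaling 2 members were lower and 1 higher, and ECI1 was not called (limma adjusted p = 0.0787). The ECI1 call also ended with mitochondrial reads left out of the totals (limma adjusted p = 0.0537), without a filter (0.128) and without any library but control replicate 1 (0.0649 at the lowest). This list was not called (adjusted p = 0.317 by camera).

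Few markers of other cell types reached the tested level. Of 3 tested fibroblast markers only COL1A1 rose, at 3.07 ± 0.232 and 3.83 ± 0.152 RPKM, a call that ended without a filter, GDF5 replicate 2 or GDF5 replicate 3, or 1 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.798 by camera, direction higher), with a median of -0.075 and a mean of 0.0052. Of immune markers only CSF1R was tested, at 1.24 ± 0.0711 and 1.51 ± 0.0529 RPKM, and it was not called (limma adjusted p = 0.0746) but was called with median-of-ratios scaling (limma adjusted p = 0.0408) and adjusted over the list alone. The podocyte marker SYNPO was at 7.78 ± 0.239 and 8.02 ± 0.244 RPKM, a log2 change of 0.038, and was not called. PLA2R1 had a log2 change of -0.19 and was not called, but it was called lower with the filter on reads (limma adjusted p = 0.0329) and with limma-voom (limma adjusted p = 0.00202), and the authors' deposited table gave it an adjusted p of 0.0263. No marker of endothelial cells or of loop, distal tubule and collecting duct cells reached the tested level, with ENG at 0.322 ± 0.0399 and 0.411 ± 0.0504 RPKM and GATA3 at 0.454 ± 0.0263 and 0.625 ± 0.0780 RPKM.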

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

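Median-of-ratios scaling, totals without mitochondrial reads and limma-voom were chosen after seeing the data. The planned DESeq2 Wald test and DESeq2 size factors were not run; the deposited values used here were RPKM, and the recovered reads were tested with limma-voom instead. The number of genes changed (3116) stayed within 1.5-fold with a pseudocount of 0.1, the read filter, the block, both added scalings and limma-voom; of these genes 2175 were called in the same direction with median-of-ratios scaling. It was 1812 without a filter (590 higher, 1222 lower), where 34157 genes were tested, and 1285 at an adjusted p under 0.01 (413 higher, 872 lower), which is stricter by construction. The read filter replaced the RPKM filter and tested more genes, 14371. Median-of-ratios scaling gave 1606 higher and 1242 lower, and limma-voom with it gave 1997 higher. The count of at least 2-fold changes was 68 with the pseudocount of 0.1, 88 with limma-voom and 87 with limma-voom and median-of-ratios scaling, against 34; a pseudocount of 1 shrinks low genes by construction. Leaving out 1 library gave 1760 to 3099 changed, 538 to 940 higher, 1222 to 2159 lower, 34 to 43 at least 2-fold and 7 to 9 lists. The largest moves came without GDF5 replicate 2 (1760), GDF5 replicate 3 (1866) and control replicate 1 (2072), while 3099 genes changed without GDF5 replicate 1, which stood apart in its group; the cause was not tested.

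With an estimated correlation 3 lists were called and with fry, which does not compare a list with other genes, 17, against 9. Fry called cholesterol synthesis lower (adjusted p = 0.0309), where camera's uncalled direction was higher. The replicate block gave 2167 changed genes, 659 higher and 1508 lower, 37 at least 2-fold and 8 lists; it ended the call of epithelial junction and keratin genes (adjusted p = 0.0610) and those of ECI1 (0.0599) and SREBF2 (0.0618), and of no other named gene. Same-numbered libraries had correlations of -0.0368, 0.0572 and -0.0311, against -0.0565 to 0.0732 for the other pairs, so no sign of pairing by number was seen. The values were centred within groups of 3 libraries, so the correlations largely cancel and a small shared effect cannot be excluded. None of the named genes tested in a setting (103 under the read filter, 107 in the others) changed direction past the threshold in any setting run; without a filter 13 lost their call and with median-of-ratios scaling 5. Without a filter 4 further lists were lower by camera: injury and repair (adjusted p = 0.00674), NF-kappaB (0.00604), interferon (0.0486) and DNA replication (0.00604). With the filter and an estimated correlation their adjusted p were 0.294, 0.348, 0.357 and 0.357. Camera compares a list with all other genes, whose median log2 change was -0.0135 without a filter and -0.050 with it. That difference alone can make lists of expressed genes lower without a filter. Depth limits genes with few reads, such as the small RNA genes, but others below the tested level, such as SMAD9 with a mean of 243 reads, were left out by their level.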

Other observations

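All tests of explanations in this part were chosen, or their limits changed, after the results had been seen. The genes BTG1, BCL2L11, TXNIP, SOD2, KLHL24, IRS2, F3 and NUAK2 were also singled out after their values were seen.

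Genes that FOXO transcription factors are known to activate were among the lower ones. BTG1, an antiproliferative gene, had a log2 change of -1.02, the pro-apoptotic gene BCL2L11 -0.80 and TXNIP, an inhibitor of thioredoxin, -0.77. A hypothesis is that FOXO targets may fall as a group. Of the other 15 tested members of a list written for this purpose 8 fell, among them SOD2 (-0.63) and KLHL24 (-0.38), and 1, IRS2 (0.45), rose. They were lower by camera on ratio-scaled values (p = 0.0270), but p = 0.0776 with an estimated correlation and a median interval of -0.27 to 0.059 leave the hypothesis weak.

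ANKRD1 (1.29) and CCN2 (0.54), known targets of YAP and TEAD, rose, while F3 (-0.97) and NUAK2 (-0.85), also targets, fell. Of the 19 other tested targets 6 rose and 2 fell, and they were higher by camera on ratio-scaled values (p = 0.0359), with p = 0.0848 with an estimated correlation. Their median ratio-scaled log2 change was 0.074 (interval -0.050 to 0.21). With ANKRD1, CCN2, F3 and NUAK2 included the camera p was 0.0518, and leaving them out was decided after that p was seen, so a general rise of these targets remains a weak hypothesis.

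More genes fell than rose, 2183 against 933. Median-of-ratios scaling gave 56.4% higher, but it sets the median change near 0 and so largely fixes the balance of calls, which leaves scaling by total reads open as an explanation. Leaving mitochondrial reads out of the totals gave 41.9% higher, which argues against the larger mitochondrial share as the whole cause. Whether total RNA per cell differed was not measured, so a general fall stays open.

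Mitochondrial DNA-encoded transcripts were higher. Their median log2 change was 0.36, and 0.42 with median-of-ratios scaling. That scaling moved the median change of all tested genes up, from -0.050 to 0.0021. It could therefore not have lowered the rise, and it does not test scaling by total reads as an explanation. With median-of-ratios scaling the 47 tested nuclear-encoded respiratory chain genes had a median of -0.048 (interval over resampled genes -0.098 to 0.017), with 4 called higher and 4 lower. In these libraries this argues against a joint rise of nuclear and mitochondrial genes. The mitochondrial rise was unequal: with the same scaling, over the 9 genes that do not overlap another, the SD of the log2 changes was 2.82 times their standard error, from 0.23 for MT-CO1 to 0.79 for MT-ND6, which argues against one common rise. A shift toward short RNAs is not borne out below 1000 bp, where 86 nuclear genes differed from longer ones by -0.015 (interval -0.090 to 0.024). Below 500 bp only 5 genes could be compared (0.028, interval -0.91 to 0.36), too few to decide. MT-ND5 (1812 bp of exon) and MT-ND6 (525 bp) also rose, by 0.42 and 0.79 with median-of-ratios scaling. A shift below 500 bp does not cover them and stays open only for shorter mitochondrial genes. The overlapping genes MT-ATP8 and MT-ND4L rose unequally, by 0.98 and 0.22 with the same scaling, the highest and lowest of the 13. Within a library the log2 ratio of MT-ATP8 to MT-ND4L was -1.19 ± 0.12 in control and -0.43 ± 0.042 in GDF5 libraries (SD, n = 3 each). Because both overlap another gene, this ratio does not separate length from counting. An effect of GDF5 on mitochondrial transcripts, a change in fragment length acting on overlapping genes such as MT-ATP8, and a difference in RNA preparation between groups all stay open as untested hypotheses.

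Small RNA genes were 4 of the 20 largest named changes, each with a mean of 6.83 to 11.7 reads. Limma-voom called 4 of them and 0 were called in the authors' deposited table, so 0 were called by both. Few reads behind the values and a real change therefore cannot be told apart, since the tests that weigh depth disagree. Of 252 tested small RNA genes 30 were called here, 17 by limma-voom and 1 in the authors' deposited table.

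The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05, since the real split alone is 1 of 10. The real split gave 3116 changed, 933 higher, 2183 lower and 34 at least 2-fold by limma. The highest of the other splits gave 0 in each case. Each other split mixed control and GDF5 libraries in both groups. A treatment effect would then widen the spread within groups and lower these counts, so the 0 does not measure chance. For gene lists the real split gave 9 and the highest of the others 6. The groups did not overlap for 5477 of the tested genes, 43.9%, against 10% by chance for a single gene if the libraries were interchangeable. These were RPKM values without median-of-ratios scaling, whose divisors were 1.02 to 1.03 in control and 0.980 to 0.985 in GDF5 libraries. Such an offset can set the groups apart for genes with little spread. Genes also vary together over 6 libraries, so the share does not measure chance either.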
